A study of Mus musculus with 19 samples.

How the data were processed

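RNA from 19 samples of NIH3T3 cells was measured on Affymetrix whole-genome mouse expression arrays, 1 array per sample. Per the labels the values are MAS5 signal intensity, a linear scale, scaled by the authors so that the mean without the highest and lowest 2% of values was 500 on every array. The MAS5 version and presence calls were not given in the sources used here. Of 45101 probe sets, 64 were controls, 34945 mapped to 1 gene in the mouse annotation, 932 to several and 9160 to none. Of those with 1 gene, 204 were not in the mouse gene reference and kept their symbol, and 0 symbols were updated. Signal is not comparable between probe sets, because probes differ in affinity. The number of arrays limits precision: groups held 1 or 2 samples, so the fit had 7 residual degrees of freedom, with 7.48 prior degrees of freedom added by limma. Gapdh 3'/5' signal ratios were 0.698 to 0.8 and Actb ratios 1.16 to 1.47. Replicates of a state correlated across probe sets with r from 0.961 to 0.971, and quiescent replicates 1a and 1b with r = 0.966 and a median absolute log2 difference of 0.316; probe sets are not independent replicates.

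Signals were taken to log2 after adding 13.6, the 20th percentile of all values, which understates changes of low genes. Quiescent replicates 1a and 1b were averaged, giving 18 columns in 11 groups. Probe sets above the 40th percentile of their array on at least 2 arrays were kept (34537), and each of 14996 genes was represented by its probe set of highest mean; 7114 genes had more than 1 probe set kept, and 19 had probe sets called in opposite directions for the average U0126 effect. All groups were fitted together with limma 3.58.1 in R 4.3.3 (eBayes with a variance trend), contrasts were tested two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with 0.05 as the limit. The difference of the U0126 effect between 4, 7 and 12 h was tested with limma's F test. Whether experiment numbers in the labels pair the samples was checked from the correlation of replicate deviations between 21 pairs of groups. It lay between 0.124 and 0.304 (median 0.21), so samples of the same number were taken as paired. Each comparison and its fixed gene lists were also computed with the experiment as a block (6 residual degrees of freedom). Gene sets chosen at other times and lists added later were not. Calls come from the fit without the block, which ignores the pairing, unless the block is named.

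In total 24 gene lists from textbook knowledge, 13 fixed genes, the comparisons, the rule for naming genes and the alternatives were chosen before the data were examined. The lists were immediate-early genes, ERK targets, G1/S, G2/M, antiproliferative genes, ribosome biogenesis, cholesterol synthesis, glycolysis, matrix, matrix proteases, actin and SRF targets, FOXO targets, p53 targets, stress response, inflammation, interferon, receptors, circadian clock, reference genes, and markers of macrophages, epithelium, endothelium, muscle and adipocytes. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Some genes sit in several lists, such as Ccng2 (antiproliferative and FOXO) and Gadd45a (antiproliferative and stress). Shifts of such lists are not independent of each other. The naming rule took, among called genes that moved the same way in both experiments and whose higher group exceeded the median of all values, the 12 largest changes each way for the average U0126 effect, 5 each way for other comparisons, the 10 smallest p-values by time, up to 4 members per list, and the 13 fixed genes, some of which go unprinted where they passed neither with nor without the block. Gene sets chosen at some times were looked at in comparisons that shared no arrays with the choice, against 10000 random sets matched on expression. All comparisons used the same spread estimate per gene, from all arrays, so counts of called genes in such sets are not independent of the choice. Figures were drawn with matplotlib 3.10.9.

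Alternatives were quantile normalization, 75th percentile scaling, offsets of 1 and 45.2 (the 40th percentile), no filter, a filter at the median on 4 arrays, no variance trend, 3 separate quiescent arrays, the probe set of highest variance, all probe sets, the experiment block, only the compared groups in the fit, and leaving out each replicate. Where 1 array was left in a group it was assumed to vary like the other groups. The workflow was tested on simulated data with known changes of 2-fold and 4-fold and with none, where no null comparison gave more than 1 call. The simulated samples had independent noise and no experiment effect. They therefore cannot show how the fit without the block behaves on paired samples. Probe sets without a single gene were kept out of the comparisons, because no gene could be named for them.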

Results

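Transcript levels were measured in NIH3T3 cells, an established line of mouse fibroblasts, on 19 whole-genome expression arrays. The cells were made quiescent by 48 h in 0.1% serum and then given basic fibroblast growth factor (FGF, 50 ng/ml) for 1, 4, 7 or 12 h. U0126, an inhibitor of MEK, the kinase that activates ERK, was used at 20 µM. It was added at -0.5 h relative to FGF, or at 1 h in an arm measured at 7 h, or at 7 h in an arm measured at 12 h. The quiescent state was measured on 3 arrays: replicates 1a and 1b of experiment 1, which were averaged, and replicate 2 of experiment 2. Each of the states at 4, 7 and 12 h, with and without U0126 from the start, had 2 arrays, from experiments 1 and 2. The states at 1 h, with and without U0126, and both late additions had 1 array each, from experiment 1. The labels do not state whether the replicates were separate cultures, so the p-values measure only the spread between samples, which may be technical. The median signal per array lay between 60.2 and 88.3, and the number of arrays limits the precision. The comparisons ask which transcripts changed with FGF between quiescence and the approach to S phase. They also ask which of those changes needed MEK activity, and whether it was needed only early or throughout. The only arrays without FGF were the quiescent ones, taken before FGF was added. Changes against quiescence therefore cannot be told apart from those of time in culture or handling. Where genes are called raised or lowered by FGF, time is included. Values are log2 differences ± SE from limma, with p-values adjusted by Benjamini-Hochberg over 14996 genes. Where the lower signal was under 45.2, the 40th percentile of all values, it was not shown to be above background, and the size and rank of the change depend on the offset. Among the genes named for the largest changes this holds for Zfp775, Lrrc8e, 4930431P19Rik, Ddias, 2900076A07Rik, Edn1, Plekha7, Il20rb, Aldh1a1, Zfp94, Npas4, Nr4a3, Tslp, Cdc6, E2f8, Cavin4, Timeless, Hdac9, 1700001G17Rik, Tnfrsf25, Npn2 and Sting1 in at least 1 comparison. A gene is said to have risen or fallen where its adjusted p was under 0.05.

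After 1 h of FGF, transcription factors of the immediate-early class rose most. The orphan nuclear receptors Nr4a3 (5.62 ± 0.63), Nr4a1 (5.20 ± 0.38) and Nr4a2 (4.69 ± 0.26) rose, as did the zinc-finger factor Egr3 (3.95 ± 0.23) and the matrix-associated protein Ccn1 (3.66 ± 0.41), with 1 array against 2 quiescent samples. Of 28 tested immediate-early genes, 19 rose and 0 fell, and 23 rose adjusted over the list alone. Their mean change was 2.10, with an adjusted p of 2.6e-52, and adjusted p = 0.014 with an estimated correlation. Egr1 rose by 2.17 ± 0.36, from 6276 ± 2490 signal units (SD, 2 experiments) to 26180, although its adjusted p became 0.1 without a variance trend. The antiproliferative gene Btg2 rose by 2.62 ± 0.34 and the survival gene Ier3 by 2.24 ± 0.19. Fos differed by 1.44 ± 0.53 and did not pass (adjusted p = 0.42), but it passed at 2.39 (adjusted p = 0.014) without quiescent replicate 2. Targets and feedback regulators of ERK were already higher: Fosl1, an AP-1 subunit, by 3.19 ± 0.28, the ERK phosphatase Dusp6 by 2.16 ± 0.20, the growth factor Ereg by 2.61 ± 0.22 and Phlda1 by 2.65 ± 0.21. In that list 5 of 21 genes rose, 9 rose and 1 fell adjusted over the list alone, and the mean was 1 (adjusted p = 6.7e-11; adjusted p = 0.049 with an estimated correlation). The prostaglandin synthase Ptgs2 rose by 2.81 ± 0.27 and the clock repressor Bhlhe40 by 2.12 ± 0.25. Myc rose by 1.11 ± 0.19, a call lost without a variance trend (adjusted p = 0.12). Among falling transcripts Ddias, which limits DNA damage-induced death, fell by 2.50 ± 0.40. Zfp775 fell by 2.75 ± 0.46, Lrrc8e by 2.65 ± 0.42 and 4930431P19Rik by 2.51 ± 0.43, but without quiescent replicate 2 their adjusted p was 0.1, 0.076 and 0.067. With the probe set of highest variance 4930431P19Rik was 0.52. For 2900076A07Rik the change was -2.43 ± 0.43, and its adjusted p was 0.082 with the offset at the 40th percentile.

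In all, 72 genes changed at 1 h, 56 higher and 16 lower. With the experiment number as a block 236 changed, 135 higher and 101 lower (42.8% lower). The count was 47 without quiescent replicate 2, 43 higher and 4 lower (8.51% lower). Under quantile normalization 83 changed, with 32.5% lower in place of 22.2%. A lone array was assumed to vary like the other groups. Cyclin D1 (Ccnd1, -0.62 ± 0.20), cyclin E1 (Ccne1, -0.32 ± 0.37), the cell-cycle inhibitors Cdkn1b (-0.38 ± 0.35) and Cdkn1a (0.41 ± 0.32), Tob1 (0.77 ± 0.32), Jund (0.11 ± 0.33), Klf4 (0.57 ± 0.22) and the ERK antagonist Spry4 (0.88 ± 0.47) did not pass at 1 h. With the experiment block Cdkn1a passed (adjusted p = 0.034).

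At 4 h ERK feedback regulators and ribosome assembly genes were among the induced transcripts, and several antiproliferative genes had fallen. The ERK phosphatases Dusp5 (3.59 ± 0.60), Dusp4 (3.49 ± 0.36) and Dusp6 (2.75 ± 0.16) rose, with Fosl1 (3.51 ± 0.23), Ereg (3.48 ± 0.18), the chromatin protein Hmga2 (3.42 ± 0.31) and the growth factor Hbegf (2.88 ± 0.23), in 2 samples against 2. Dusp6 signal went from 1322 ± 335 (SD, 2 experiments) to 8815 ± 706 (SD, 2 arrays). Of 21 ERK targets 13 rose and 0 fell, 14 rose adjusted over the list alone, and the mean was 1.63 (adjusted p = 7.3e-23; adjusted p = 0.011 with an estimated correlation). Ribosome biogenesis genes rose in 26 of 31 cases, 28 adjusted over the list alone, with a mean of 0.89 (adjusted p = 1.7e-30; adjusted p = 0.013 with an estimated correlation). They included Nolc1 (1.30 ± 0.14), Nop2 (1.32 ± 0.15) and Rrs1 (1.09 ± 0.14), and the polyamine enzyme Srm rose by 1.32 ± 0.13. The antiproliferative list, which may hold genes chosen by the study from such samples and is then not independent evidence, averaged -0.68 (adjusted p = 1.1e-10; adjusted p = 0.023 with an estimated correlation). Of its 36 genes 15 fell, 24 adjusted over the list alone. The p53-induced gene Trp53inp1 fell by 1.93 ± 0.16, the DNA damage gene Gadd45a by 1.31 ± 0.18, the cyclin-like Ccng2 by 1.60 ± 0.25 and the AP-1 subunit Jund by 1.73 ± 0.27. Of 15 FOXO targets 6 fell, 9 adjusted over the list alone, with a mean of -0.79 (adjusted p = 0.013 with an estimated correlation). They included the PI3K inhibitor Pik3ip1 (-1.79 ± 0.21) and the ubiquitin ligase Fbxo32 (-1.61 ± 0.24). Interferon-response genes averaged -0.78, with 6 of 15 lower and 8 adjusted over the list alone (adjusted p = 0.022 with an estimated correlation), and Ifit3 fell by 1.58 ± 0.22. The largest falls were in endothelin 1 (Edn1, -3.32 ± 0.40), the clock-output factor Dbp (-2.87 ± 0.30), Aff3 (-2.73 ± 0.29), Plekha7 (-2.70 ± 0.53) and Il20rb (-2.51 ± 0.51), the last with an adjusted p of 0.067 without FGF 4 h replicate 2. The chemokine Ccl2 (2.62 ± 0.28), the urokinase receptor Plaur (2.60 ± 0.14), the hexokinase Hk2 (1.58 ± 0.18) and the cystine transporter Slc7a11 (1.64 ± 0.24) rose.

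In total 1336 genes changed at 4 h, 588 higher and 748 lower, each in the same direction in both experiments. The same arrays made the call, so a shared direction largely follows from it and is no separate support. This holds for the other comparisons too. The excess of lower genes turned over under 75th percentile scaling (694 higher, 597 lower), among all probe sets (903 and 893) and without quiescent replicate 2 (308 and 260). With the experiment block 2658 changed. Counts were 568 without quiescent replicate 2, 759 without FGF 4 h replicate 1 and 548 without FGF 4 h replicate 2.

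By 7 h the genes of DNA replication had begun to rise. The replication licensing factor Cdt1 rose by 1.55 ± 0.15, the helicase subunit Mcm3 by 2.01 ± 0.23 and the methylation maintenance factor Uhrf1 by 1.94 ± 0.23, in 2 samples against 2. Of 47 G1/S genes 30 rose and 0 fell, 36 rose adjusted over the list alone, and the mean was 1.05 (adjusted p = 1.6e-25; adjusted p = 0.03 with an estimated correlation). The cytokine Tslp (3.86 ± 0.31), Hmga2 (3.68 ± 0.31), Ereg (3.61 ± 0.18), Fosl1 (3.34 ± 0.23) and the receptor Gpr149 (3.05 ± 0.34) rose most. ERK targets averaged 1.55, with 13 of 21 higher and 13 adjusted over the list alone (adjusted p = 0.011 with an estimated correlation). Ribosome biogenesis genes averaged 0.93, with 25 of 31 higher and 27 adjusted over the list alone (adjusted p = 0.017 with an estimated correlation), among them Fbl (1.24 ± 0.13), and the polyamine enzymes Odc1 (1.5 ± 0.14) and Srm (1.35 ± 0.13) rose. The antiproliferative list averaged -0.83, with 21 of 36 lower and 23 adjusted over the list alone (adjusted p = 0.017 with an estimated correlation). In it Trp53inp1 (-2.12 ± 0.16), Ccng2 (-2.21 ± 0.25), Gadd45a (-1.63 ± 0.18) and Jund (-2.37 ± 0.27) fell, Jund from 7537 ± 3100 (SD, 2 experiments) to 1385 ± 192 signal units (SD, 2 arrays). FOXO targets averaged -0.97, with 8 of 15 lower and 9 adjusted over the list alone (adjusted p = 0.011 with an estimated correlation), and Pik3ip1 fell by 2.60 ± 0.21. Interferon genes averaged -0.65, with 7 of 15 lower and 7 adjusted over the list alone (adjusted p = 0.03 with an estimated correlation), and Gbp2 fell by 2.36 ± 0.21. Dbp (-3.51 ± 0.30), the protease inhibitor Serpinb1a (-3.21 ± 0.25), the linker histone H1f2 (-3.19 ± 0.32), the steroid-metabolizing Akr1c14 (-3.17 ± 0.53) and Ccn5 (-2.97 ± 0.20) fell most. The clock genes Per3 (-2.61 ± 0.33) and Nr1d1 (-2.25 ± 0.39) also fell. Among matrix-remodelling genes the membrane metalloprotease Mmp14 fell by 1.24 ± 0.15 and Plaur rose by 2.71 ± 0.14.

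The total at 7 h was 1898 genes, 818 higher and 1080 lower, each in the same direction in both experiments. Under 75th percentile scaling 929 were higher and 878 lower. The experiment block gave 3250. Counts were 868 without quiescent replicate 2 and 1024 without FGF 7 h replicate 1.

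At 12 h transcripts of S phase entry were among the largest rises. The origin-licensing factor Cdc6 (4.23 ± 0.44), thymidine kinase (Tk1, 3.94 ± 0.46), Hmga2 (3.77 ± 0.31), cyclin E2 (Ccne2, 3.71 ± 0.33) and the exonuclease Exo1 (3.69 ± 0.30) rose most, in 2 samples against 2. Cdc6 signal went from 84.02 ± 11.6 (SD, 2 experiments) to 1806 ± 187 (SD, 2 arrays). All 47 tested G1/S genes rose, also adjusted over the list alone (47), with a mean of 2.51 (adjusted p = 1.3e-52; adjusted p = 0.012 with an estimated correlation). Mcm3 (3.46 ± 0.23), Uhrf1 (3.46 ± 0.23), Mcm4 (2.24 ± 0.14) and Cdt1 (2.18 ± 0.15) were among them. Mitotic genes followed: 23 of 33 G2/M genes rose, 27 adjusted over the list alone, with a mean of 1.66 (adjusted p = 1.6e-17; adjusted p = 0.14 with an estimated correlation). The checkpoint kinase Bub1 rose by 2.78 ± 0.29, Cdk1 by 2.50 ± 0.27, cyclin A2 (Ccna2) by 2.32 ± 0.26 and Cks2 by 1.93 ± 0.18. Enzymes of cholesterol synthesis rose in 17 of 20 cases, 19 adjusted over the list alone, with a mean of 1.01 (adjusted p = 1.3e-15; adjusted p = 0.079 with an estimated correlation). They included Lss (1.70 ± 0.19), Sc5d (1.38 ± 0.15), Idi1 (1.35 ± 0.16) and Cyp51 (1.03 ± 0.12). The antiproliferative list averaged -1, with 22 of 36 lower and 25 adjusted over the list alone (adjusted p = 0.019 with an estimated correlation). They included Ccng2 (-2.44 ± 0.25), Trp53inp1 (-2.13 ± 0.16), the MYC antagonist Mxd4 (-1.99 ± 0.19) and Hbp1 (-1.72 ± 0.15). FOXO targets averaged -1.07 (9 of 15 lower; 9 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation) and interferon genes -0.88 (6 of 15 lower; 6 adjusted over the list alone; adjusted p = 0.032 with an estimated correlation). ERK targets averaged 1.39 (12 of 21 higher; 13 adjusted over the list alone; adjusted p = 0.02 with an estimated correlation) and ribosome biogenesis genes 0.86 (22 of 31 higher; 25 adjusted over the list alone; adjusted p = 0.035 with an estimated correlation). The retinal dehydrogenase Aldh1a1 (-3.83 ± 0.43), Akr1c14 (-3.70 ± 0.53), Ccn5 (-3.65 ± 0.20), Serpinb1a (-3.64 ± 0.25) and Dbp (-3.53 ± 0.30) fell most.

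Extracellular matrix genes were lower in 13 of 27 cases at 12 h, and 1 was higher, with 14 lower and 1 higher adjusted over the list alone (mean -0.42; adjusted p = 0.35 with an estimated correlation). The thrombospondin Thbs2 fell by 1.40 ± 0.25, the protease inhibitor Timp3 by 1.07 ± 0.19 and the collagen Col5a1 by 1.07 ± 0.19, and the growth factor receptor Pdgfrb fell by 1.37 ± 0.20. The clock genes Per3 (-3.01 ± 0.33) and Tef (-2.15 ± 0.24) fell, and the circadian list averaged -1.07 (adjusted p = 0.18 with an estimated correlation). In sum 3048 genes changed at 12 h, 1280 higher and 1768 lower, each in the same direction in both experiments. With the experiment block the count was 4506. It was 1733 without quiescent replicate 2, 1992 without FGF 12 h replicate 1 and 1994 without FGF 12 h replicate 2. Differences between the FGF times were not tested.

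Against quiescence Egr1 was -0.62 ± 0.29 at 4 h (adjusted p = 0.23; 0.034 without quiescent replicate 1a) and fell by 1.74 ± 0.29 at 7 h and fell by 2.19 ± 0.29 at 12 h. Fos fell by 2 ± 0.43 at 4 h, where its adjusted p was 0.11 without quiescent replicate 2, 0.078 without quiescent replicate 1b and 0.064 without FGF 4 h replicate 1. It fell by 2.57 ± 0.43 at 7 h and 2.83 ± 0.43 at 12 h. Myc was higher at 4 h (1.02 ± 0.16) and 7 h (0.77 ± 0.16). Its smaller rise at 12 h (0.50 ± 0.16, adjusted p = 0.037) was lost without quiescent replicate 1a (0.11), FGF 12 h replicate 1 (0.063) or replicate 2 (0.22), without a variance trend (0.1) and with the probe set of highest variance (0.066). Ccnd1 rose by 0.80 ± 0.16 at 4 h (adjusted p = 0.074 without FGF 4 h replicate 1) and by 1.33 ± 0.16 at both 7 and 12 h. Ccne1 was 0.71 ± 0.30 at 4 h without passing (adjusted p = 0.18), rose by 1.56 ± 0.30 at 7 h and by 3.34 ± 0.30 at 12 h. Cdkn1b fell by 1.18 ± 0.28, 1.04 ± 0.28 and 1.10 ± 0.28 at 4, 7 and 12 h. These calls were lost without quiescent replicate 2 at 4 h (adjusted p = 0.053) and 7 h (0.066), without FGF 7 h replicate 1 (0.068), without replicate 2 of FGF at 4 h (0.19), 7 h (0.12) and 12 h (0.13), and without a variance trend (0.08, 0.096 and 0.057). Cdkn1a fell by 0.93 ± 0.26 at 4 h (adjusted p = 0.038), but its adjusted p was 0.35 without quiescent replicate 2, 0.057 without quiescent replicate 1b, 0.27 without FGF 4 h replicate 1, 0.14 without a variance trend, 0.056 without a filter and 0.27 with the probe set of highest variance. At 7 h Cdkn1a was -0.81 ± 0.26 (adjusted p = 0.053) and at 12 h -0.70 ± 0.26 (adjusted p = 0.073), and with the experiment block the adjusted p was 5.8e-05 and 0.00015. Tob1, an antiproliferative BTG family gene, was -0.77 ± 0.26, -0.51 ± 0.26 and -0.53 ± 0.26 without passing (adjusted p = 0.082, 0.26 and 0.18), and with the block its adjusted p was 0.00028, 0.0067 and 0.0033. Klf4 fell by 0.74 ± 0.18, 0.84 ± 0.18 and 1.11 ± 0.18. The adjusted p of Klf4 without quiescent replicate 2 was 0.14 at 4 h and 0.065 at 7 h, without replicate 2 of FGF 0.18 at 4 h and 0.077 at 7 h, and at 4 h it was 0.16 with the probe set of highest variance. The call of Klf4 at 4 h was also lost without a variance trend. With the experiment block these calls held: the adjusted p of Cdkn1b was 0.00062, 0.0013 and 0.00051 at 4, 7 and 12 h. For Cdkn1a at 4 h it was 2.5e-05, for Klf4 at 4 and 7 h 0.0014 and 0.00032, and for Myc at 12 h 0.0061. Spry4 (0.65 ± 0.38, 0.55 ± 0.38 and 0.46 ± 0.38) did not pass. Dusp6 was 2.51 ± 0.16 higher at 7 h and 2.37 ± 0.16 at 12 h, Fosl1 was 3.23 ± 0.23 higher at 12 h, and Jund fell by 2.30 ± 0.27 at 12 h.

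**Figure D1:**
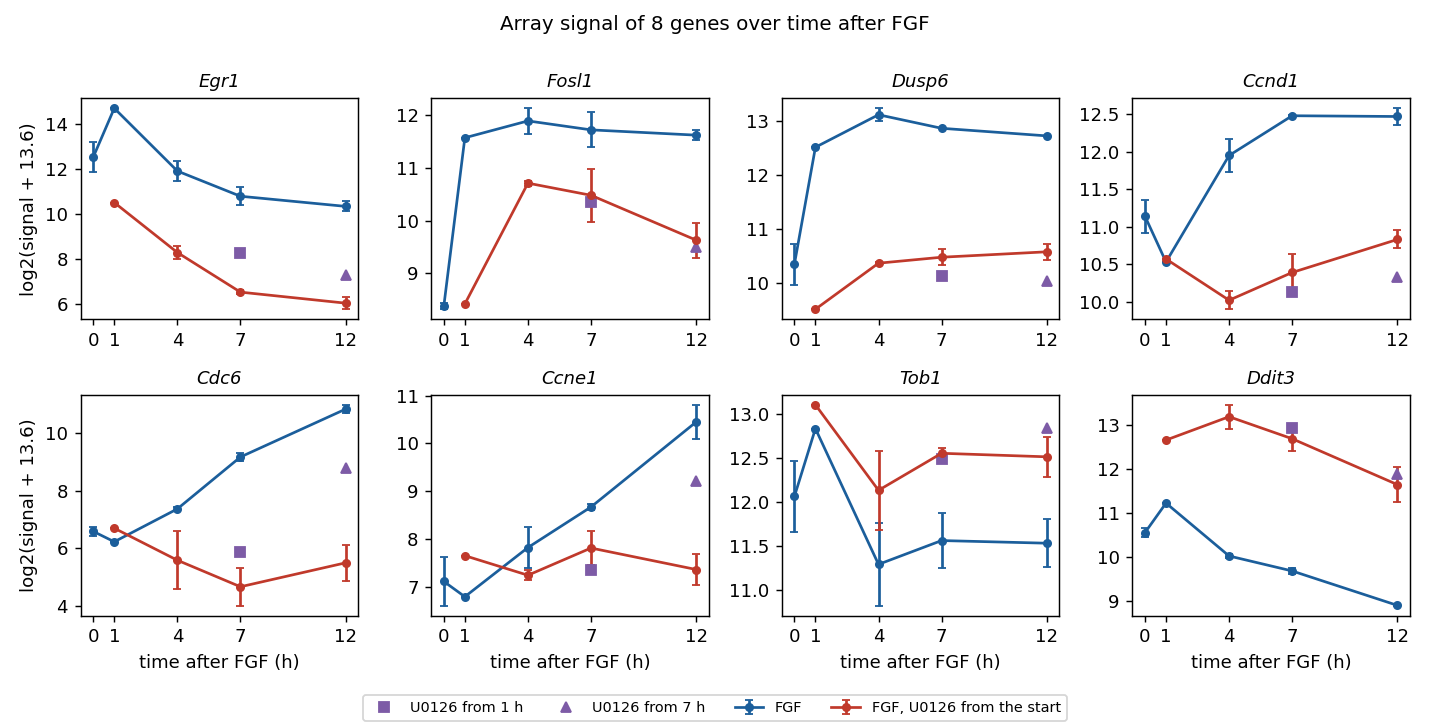
Array signal of 8 genes on a log2 scale (log2 of signal plus 13.6) against hours of FGF, with lines for FGF alone and FGF with U0126 from the start (mean ± SD over replicates) and single markers for U0126 added at 1 or 7 h. Cdc6 reached 1806 at 12 h of FGF and 33.95 with U0126, while Ddit3 at 4 h was 1024 with FGF and 9326 with U0126.

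Given from the start, U0126 lowered ERK targets and G1/S transcripts and raised stress-response genes, in the average effect over 4, 7 and 12 h (6 samples with against 6 without, in 6 pairs). The chemokine Ccl2 (-4.29 ± 0.16), Egr1 (-4.06 ± 0.17), Cdc6 (-3.87 ± 0.25), Tslp (-3.68 ± 0.18), Hmga2 (-3.63 ± 0.18), Ereg (-3.34 ± 0.10), Gpr149 (-3.26 ± 0.20), the repressor of the E2F family E2f8 (-3.18 ± 0.26), the kinase Prkg2 (-2.89 ± 0.09), the ETS factor Etv5 (-2.88 ± 0.12), the fork-protection gene Timeless (-2.82 ± 0.32) and Uhrf1 (-2.78 ± 0.13) fell most. The genes that rose most were Nr4a3 (4.25 ± 0.30), the stress-induced factor Atf3 (3.64 ± 0.13), the carbonic anhydrase Car6 (3.34 ± 0.23), the globin Hbb-bh1 (3.16 ± 0.16), the activity-regulated factor Npas4 (3.10 ± 0.26), Mef2c (2.98 ± 0.14), Ddit3 (2.96 ± 0.11), the pseudokinase Trib3 (2.70 ± 0.15), Gadd45a (2.56 ± 0.11), the cytokine Il6 (2.54 ± 0.36), Nr4a1 (2.48 ± 0.18) and Paqr3 (2.48 ± 0.15). ERK targets fell in 15 of 21 cases, 16 adjusted over the list alone, and averaged -1.31 (adjusted p = 3.2e-17; adjusted p = 0.012 with an estimated correlation), with Dusp6 at -2.42 ± 0.09, Fosl1 at -1.47 ± 0.13 and Ccnd1 at -1.89 ± 0.09. Spry4 was -0.53 ± 0.22 and did not pass (adjusted p = 0.11), but passed with the probe set of highest variance (-1.45, 0.011) and without FGF 7 h replicate 1 (-0.69, 0.033). All 47 G1/S genes fell, also adjusted over the list alone (47), with a mean of -1.53 (adjusted p = 1e-46; adjusted p = 0.012 with an estimated correlation). They included Mcm5 (-2.68 ± 0.16), Mcm7 (-1.75 ± 0.10), Mcm4 (-1.66 ± 0.08) and Ccne1 (-1.51 ± 0.18). The stress-response list rose in 22 of 24 cases, 23 adjusted over the list alone, with a mean of 1 (adjusted p = 3.8e-20; adjusted p = 0.012 with an estimated correlation). They included the glutathione-degrading Chac1 (2.41 ± 0.17) and the amino acid transporter subunit Slc3a2 (1.17 ± 0.08).

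In the antiproliferative list more genes rose than fell with U0126 in that average, and others did not pass. Jund rose by 2.29 ± 0.16, Trp53inp1 by 1.62 ± 0.09, Tob1 by 0.94 ± 0.15, Cdkn1a by 0.93 ± 0.15, Klf4 by 0.90 ± 0.11 and Cdkn1b by 0.73 ± 0.16. Other members went down, such as the endocytic adaptor Dab2 (-0.94 ± 0.08) and the translation inhibitor Pdcd4 (-0.46 ± 0.08). In the antiproliferative list 17 of 36 rose and 5 fell, 18 and 5 adjusted over the list alone, with a mean of 0.47 (adjusted p = 0.00011; adjusted p = 0.14 with an estimated correlation). Of 33 G2/M genes 26 fell, 30 adjusted over the list alone (mean -0.98; adjusted p = 1.1e-15; adjusted p = 0.16 with an estimated correlation). They included Ndc80 (-2.26 ± 0.29), Bub1 (-1.55 ± 0.17), Ccna2 (-1.41 ± 0.15) and Cks2 (-1.22 ± 0.10). Ribosome biogenesis genes fell in 18 of 31 cases, 22 adjusted over the list alone (mean -0.36; adjusted p = 2.1e-10; adjusted p = 0.14 with an estimated correlation), with Polr1b at -0.77 ± 0.12 and Nolc1 and Fbl both at -0.70 ± 0.08. Inflammatory genes divided, with 7 of 12 lower and 2 higher, the same numbers adjusted over the list alone (mean -0.75; adjusted p = 0.00026; adjusted p = 0.22 with an estimated correlation). The chemokine Ccl7 (-2.75 ± 0.18), the adhesion molecule Vcam1 (-1.34 ± 0.13) and the growth factor Csf1 (-0.89 ± 0.08) fell, and Ptgs2 rose by 0.58 ± 0.13. The p53 target list had 9 of 16 higher and 1 lower, 9 and 2 adjusted over the list alone (mean 0.63; adjusted p = 0.00017; adjusted p = 0.16 with an estimated correlation), with Plk2 at 1.29 ± 0.09 and Pmaip1 at 1.17 ± 0.16. Clock genes rose in 6 of 17 cases, 7 adjusted over the list alone (mean 0.54; adjusted p = 0.00096; adjusted p = 0.22 with an estimated correlation). They included Nfil3 (2.26 ± 0.14) and Dbp (1.30 ± 0.17). Receptor genes fell in 7 of 15 cases and 1 rose, 9 and 1 adjusted over the list alone (mean -0.39; adjusted p = 7e-05; adjusted p = 0.14 with an estimated correlation), with Pdgfra at -1.23 ± 0.10 and Met at -0.58 ± 0.08. Interferon genes rose in 6 of 15 cases, 6 adjusted over the list alone (mean 0.31; adjusted p = 0.017; adjusted p = 0.14 with an estimated correlation), Ifit3 by 1.61 ± 0.12. Of 18 actin and SRF targets 1 rose and 3 fell, the same numbers adjusted over the list alone (mean -0.21; adjusted p = 0.046; adjusted p = 0.59 with an estimated correlation), with Ccn2 at -1.63 ± 0.16.

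Immediate-early genes split, with 11 of 28 higher and 12 lower, 12 and 13 adjusted over the list alone. Egr3 fell by 2.63 ± 0.11 and Egr2 by 2.03 ± 0.25 while Nr4a3, Nr4a1 and Atf3 rose. The list's mean was 0.09, its median -0.24 and the test's direction down (adjusted p = 0.66). Fos, at -0.33 ± 0.25, did not pass (adjusted p = 0.42), and Myc fell by 0.36 ± 0.09 (adjusted p = 0.01). The lists for FOXO targets (mean 0.11, adjusted p = 0.17), cholesterol synthesis (0.01, 0.66), glycolysis (0.07, 0.73), matrix (0.05, 0.73), matrix proteases (-0.20, 0.27) and reference genes (-0.05, 0.59) did not shift. As single genes the protease Mmp14 rose by 1.64 ± 0.08 while the protease inhibitor Timp1 fell by 1.64 ± 0.08 and Plaur fell by 1.18 ± 0.08. Marker lists of other cell types, for macrophages (-0.11, 0.45), epithelium (0.35, 0.17), endothelium (-0.04, 0.86), muscle (-0.27, 0.45) and adipocytes (mean 0.09, median -0.20, 0.45), did not shift either. The average effect covered 3296 genes, 1752 higher and 1544 lower, of which 2742 (83.2%) moved the same way in all 6 pairs. The experiment block gave 4592, and the count without 1 array lay between 2833 and 3137.

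**Figure D2:**
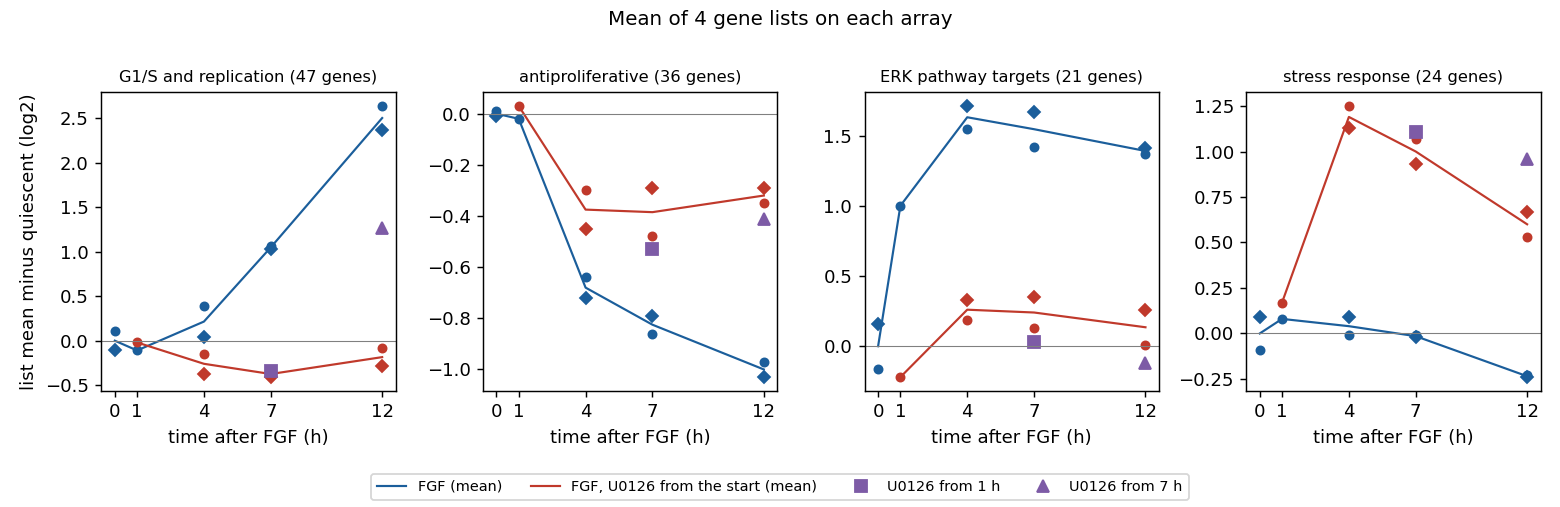
Mean log2 difference from quiescent cells of 47 G1/S genes, 36 antiproliferative genes, 21 ERK targets and 24 stress-response genes on each array, by hours of FGF, with circles for experiment 1 and diamonds for experiment 2. At 12 h the G1/S mean was 2.51 with FGF, -0.18 with U0126 from the start and 1.27 with U0126 from 7 h.

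Genes that differed from quiescence at a given time of FGF were shifted the opposite way by U0126 at other times. These comparisons share no arrays with the selection. The 588 genes raised by FGF at 4 h, such as Hmga2, Ereg and Dusp6, had a median U0126 effect of -0.31 at 7 h, with 152 lower against 17.9 expected for random genes, and -0.42 at 12 h, with 217 lower against 34.1 expected. The 818 genes raised at 7 h had medians of -0.33 at 4 h (190 lower, 22.4 expected) and -0.48 at 12 h (354 lower, 47.4 expected). For the 1280 genes raised at 12 h, among them Cdc6, Tk1 and Ccne2, the medians were -0.22 at 4 h (189 lower, 35 expected) and -0.34 at 7 h (266 lower, 39 expected). The 748 genes lowered by FGF at 4 h, such as Trp53inp1 and Jund, had medians of 0.23 at 7 h (124 higher, 22.7 expected) and 0.43 at 12 h (249 higher, 46.8 expected). The 1080 genes lowered at 7 h gave 0.31 at 4 h (206 higher, 34.6 expected) and 0.48 at 12 h (410 higher, 67.6 expected). The 1768 genes lowered at 12 h gave 0.18 at 4 h (236 higher, 56.7 expected) and 0.20 at 7 h (243 higher, 53.8 expected). None of 10000 random sets of the same size had as extreme a median in any of these comparisons. The spread of each gene was estimated from all arrays, so the counts of called genes are not independent of the selection.

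After 1 h, U0126 held back the EGR factors and other immediate-early genes (1 array against 1, assumed to vary like the other groups). Egr2 (-5.72 ± 0.61), Egr3 (-4.78 ± 0.27), Egr1 (-4.19 ± 0.41), the EGF receptor inhibitor Errfi1 (-3.69 ± 0.34) and Fosl1 (-3.15 ± 0.32) fell most. Dusp6 (-2.99 ± 0.23), Ereg (-2.68 ± 0.26), Nr4a2 (-2.18 ± 0.30) and Phlda1 (-1.95 ± 0.25) also fell. Egr1 signal was 26180 with FGF and 1426 with U0126. The stress genes Gadd45g (2.12 ± 0.31) and Gadd45b (1.77 ± 0.21) rose, with Zfp94 (2.78 ± 0.46), the small nucleolar RNA host Snhg5 (1.47 ± 0.20) and Ddit3 (1.44 ± 0.26, adjusted p = 0.045). Snhg5 was lost without a variance trend (adjusted p = 0.052) and was -0.17 with the probe set of highest variance. Ddit3 was lost under 75th percentile scaling (0.061), without a filter (0.067), with the filter at the median (0.051), without a variance trend (0.18) and with the probe set of highest variance (0.059). Of 28 immediate-early genes 6 fell, and adjusted over the list alone 19 fell and 2 rose (mean -1.41; adjusted p = 2.5e-23; adjusted p = 0.07 with an estimated correlation). Of 21 ERK targets 5 fell, 10 adjusted over the list alone (mean -1.22; adjusted p = 1.8e-21; adjusted p = 0.014 with an estimated correlation). Fos (-1.75 ± 0.61), Myc (-0.88 ± 0.22, adjusted p = 0.19; 0.025 with the block), Ccnd1 (0.05 ± 0.23), Ccne1 (0.86 ± 0.43), Cdkn1a (-0.28 ± 0.37), Cdkn1b (0.54 ± 0.40), Tob1 (0.27 ± 0.37), Jund (0.00 ± 0.39), Klf4 (-0.69 ± 0.26) and Spry4 (-0.69 ± 0.54) did not pass. There were 27 such genes, 5 higher and 22 lower, and 158 with the block. With the block 92 were higher and 66 lower (41.8% lower). Under quantile normalization 35 changed, 71.4% lower in place of 81.5%, 38 with an offset of 1 (65.8% lower) and 21 without a variance trend (66.7% lower). The antiproliferative list (mean 0.06, adjusted p = 0.61) and the stress list (0.08, adjusted p = 0.55) did not shift at 1 h.

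With 4 h of FGF, stress genes rose with U0126 and ERK targets fell. Atf3 (4.10 ± 0.23), Mef2c (3.45 ± 0.24), Nr4a3 (3.43 ± 0.52), Ddit3 (3.16 ± 0.19) and Npas4 (3.15 ± 0.46) rose most. Trib3 (3.15 ± 0.27), Chac1 (2.90 ± 0.29), Gadd45a (2.64 ± 0.18), Jund (1.80 ± 0.27) and the alanyl-tRNA synthetase Aars (1.29 ± 0.15) also rose, in 2 samples against 2. Ddit3 signal was 1024 ± 33.5 with FGF and 9326 ± 1710 with U0126 (SD, 2 arrays each). Hmga2 (-3.65 ± 0.31), Egr1 (-3.61 ± 0.29), Ereg (-3.43 ± 0.18), the PDZ protein Pdzd2 (-3.24 ± 0.19) and Ccl2 (-3.02 ± 0.28) fell most, with Dusp6 (-2.74 ± 0.16), Etv5 (-2.66 ± 0.21) and Ccnd1 (-1.93 ± 0.16). Fosl1 fell by 1.18 ± 0.23, with an adjusted p of 0.07 without FGF 4 h replicate 1. The stress list averaged 1.15 with 16 of 24 higher and 21 adjusted over the list alone (adjusted p = 0.0099 with an estimated correlation). ERK targets averaged -1.37 with 13 of 21 lower and 14 adjusted over the list alone (adjusted p = 0.0099 with an estimated correlation). The G1/S list averaged -0.48 with 10 of 47 lower, and 13 lower and 1 higher adjusted over the list alone (adjusted p = 0.23 with an estimated correlation); Msh6 fell by 0.86 ± 0.14. In the antiproliferative list 10 rose and 2 fell, 12 and 6 adjusted over the list alone, and its mean of 0.30 did not pass (adjusted p = 0.068; 0.034 with the block). Cdkn1a rose by 1.17 ± 0.26, a call lost without FGF 4 h replicate 1 (adjusted p = 0.15), U0126 4 h replicate 2 (0.12) or a variance trend (0.086) and with the probe set of highest variance (0.26). Klf4 rose by 0.71 ± 0.18, a call lost without FGF 4 h replicate 1 (0.061), replicate 2 (0.24) or U0126 4 h replicate 1 (0.27), without a variance trend (0.13), with only the compared groups (0.074) and with the probe set of highest variance (0.38). Tob1 (0.84 ± 0.26, adjusted p = 0.075; 0.00015 with the block), Cdkn1b (0.56 ± 0.28), Ccne1 (-0.59 ± 0.30) and Myc (-0.25 ± 0.16) did not pass. With the block Cdkn1a and Klf4 passed, with an adjusted p of 1.5e-06 and 0.0025. The total was 891 genes, 481 higher and 410 lower, each in the same direction in both experiments, with 1946 with the block. It was 496 and 436 without FGF 4 h replicate 1 and replicate 2 and 477 and 539 without U0126 4 h replicate 1 and replicate 2; without U0126 4 h replicate 1 there were 236 higher and 241 lower.

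At 7 h the inhibitor also lowered the replication genes that FGF had raised. Ccl2 (-4.82 ± 0.28), Tslp (-4.51 ± 0.31), Cdc6 (-4.50 ± 0.44), Egr1 (-4.26 ± 0.29) and Hmga2 (-3.37 ± 0.31) fell most. Mcm5 (-3.06 ± 0.27), Uhrf1 (-2.98 ± 0.23), Etv5 (-2.85 ± 0.21), Ccn2 (-2.47 ± 0.27), Dusp6 (-2.37 ± 0.16), Ccnd1 (-2.09 ± 0.16) and Cdt1 (-1.60 ± 0.15) fell as well, in 2 samples against 2. Nr4a3 (5.24 ± 0.52), Car6 (3.49 ± 0.40), Atf3 (3.34 ± 0.23), Npas4 (3.10 ± 0.46) and Ddit3 (3 ± 0.19) rose most. Gadd45a (2.58 ± 0.18), Jund (2.43 ± 0.27), Mmp14 (1.87 ± 0.15), Trp53inp1 (1.82 ± 0.16) and the endoplasmic reticulum stress gene Herpud1 (1.5 ± 0.16) rose. Jund signal with U0126 was 7480 ± 120 against 1385 ± 192 with FGF alone (SD, 2 arrays each). The G1/S list averaged -1.42, with 33 of 47 lower and 42 adjusted over the list alone (adjusted p = 0.016 with an estimated correlation). ERK targets averaged -1.31, with 13 of 21 lower and 14 adjusted over the list alone (adjusted p = 0.01 with an estimated correlation). The stress list averaged 1.02, with 16 of 24 higher and 20 adjusted over the list alone (adjusted p = 0.01 with an estimated correlation). The antiproliferative list averaged 0.44, with 9 higher and 2 lower, 14 and 3 adjusted over the list alone (adjusted p = 6.5e-05; adjusted p = 0.15 with an estimated correlation). Klf4 rose by 1.00 ± 0.18 (adjusted p = 0.057 without FGF 7 h replicate 2; 0.22 with the probe set of highest variance), and Fosl1 fell by 1.24 ± 0.23 (0.06 without U0126 7 h replicate 2). Tob1 rose by 0.99 ± 0.26, a call lost without FGF 7 h replicate 2 (adjusted p = 0.25), U0126 7 h replicate 1 (0.17) or replicate 2 (0.13), without a filter (0.051) or a variance trend (0.15) and with the probe set of highest variance (0.38). Myc, at -0.58 ± 0.16 (adjusted p = 0.04), lost its call without any of the 4 arrays (0.14 and 0.15 for FGF, 0.27 and 0.073 for U0126) and under 6 other settings. Cdkn1a (0.92 ± 0.26, adjusted p = 0.05; 2.2e-05 with the block), Ccne1 (-0.86 ± 0.30, 0.13; 0.043 with the block) and Cdkn1b (0.76 ± 0.28, 0.16; 0.022 with the block) did not pass. Tob1 and Myc passed with the block, with an adjusted p of 2.2e-05 and 0.0045. In all 913 genes changed, 456 higher and 457 lower, each in the same direction in both experiments, with 1882 with the block. Counts were 600 and 520 without FGF 7 h replicate 1 and replicate 2 and 491 and 503 without U0126 7 h replicate 1 and replicate 2.

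At 12 h U0126 lowered every tested gene of the G1/S list. Cdc6 (-5.32 ± 0.44), E2f8 (-5.06 ± 0.46), Tk1 (-5.03 ± 0.46), Ccl2 (-5.02 ± 0.28) and the cohesion factor Dscc1 (-4.53 ± 0.33) fell most, in 2 samples against 2. Cdc6 and E2f8 signal with U0126, at 33.95 ± 20.2 and 19.3 ± 18.2 (SD), was near background, so their size and rank depended on the offset. Tk1 signal was 3599 ± 883 with FGF and 106.2 ± 70 with U0126 (SD). Egr1 (-4.29 ± 0.29), Uhrf1 (-3.93 ± 0.23), Bub1 (-3.47 ± 0.29), Ccne1 (-3.09 ± 0.30), the primase Prim1 (-2.89 ± 0.17), Mcm7 (-2.84 ± 0.17), Ccna2 (-2.68 ± 0.26), Dusp6 (-2.14 ± 0.16), Fosl1 (-1.98 ± 0.23) and Ccnd1 (-1.64 ± 0.16) fell too. All 47 G1/S genes fell, also adjusted over the list alone (47), with a mean of -2.69 (adjusted p = 3.6e-72; adjusted p = 0.0094 with an estimated correlation). Of 33 G2/M genes 27 fell, 32 adjusted over the list alone (mean -1.92; adjusted p = 2.6e-26; adjusted p = 0.072 with an estimated correlation). Car6 (4.19 ± 0.40), Nr4a3 (4.09 ± 0.52), Hbb-bh1 (3.95 ± 0.28), Aldh1a1 (3.64 ± 0.43) and Atf3 (3.49 ± 0.23) rose most. Ddit3 (2.74 ± 0.19), Jund (2.66 ± 0.27), Gadd45a (2.47 ± 0.18), Ifit3 (1.94 ± 0.22), Pik3ip1 (1.86 ± 0.21) and Trp53inp1 (1.72 ± 0.16) also rose. The antiproliferative list averaged 0.67, with 13 of 36 higher and 1 lower, 19 and 2 adjusted over the list alone (adjusted p = 1.9e-08; adjusted p = 0.053 with an estimated correlation). The stress list averaged 0.83, with 14 of 24 higher, and 18 higher and 1 lower adjusted over the list alone (adjusted p = 5.5e-11; adjusted p = 0.053 with an estimated correlation). ERK targets averaged -1.25 (13 of 21 lower; 15 adjusted over the list alone; adjusted p = 0.024 with an estimated correlation) and ribosome biogenesis genes -0.51 (15 of 31 lower; 18 adjusted over the list alone; adjusted p = 0.072 with an estimated correlation). FOXO targets averaged 0.38 (4 of 15 higher; 6 adjusted over the list alone; adjusted p = 0.053 with an estimated correlation). Klf4 rose by 0.98 ± 0.18 (adjusted p = 0.2 with the probe set of highest variance). Tob1 rose by 0.98 ± 0.26, a call lost without FGF 12 h replicate 2 (adjusted p = 0.19), U0126 12 h replicate 1 (0.16) or replicate 2 (0.051), or a variance trend (0.099). Cdkn1b (0.88 ± 0.28, 0.057; 0.0049 with the block) and Cdkn1a (0.69 ± 0.26, 0.11; 0.00025 with the block) did not pass, nor did Myc (-0.24 ± 0.16). Tob1 passed with the block, with an adjusted p of 1.4e-05. The count was 1808 genes, 939 higher and 869 lower, each in the same direction in both experiments, with 3095 with the block. It was 1036 and 1039 without FGF 12 h replicate 1 and replicate 2 and 1153 and 984 without U0126 12 h replicate 1 and replicate 2. The excess of higher genes turned over under 75th percentile scaling (849 higher, 907 lower) and without a variance trend (624 and 674). It also turned over with the probe set of highest variance (532 and 625), among all probe sets (1296 and 1437) and with only the compared groups (767 and 807). The same held without FGF 12 h replicate 2 (455 and 584) and without U0126 12 h replicate 1 (527 and 626) or replicate 2 (443 and 541).

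**Figure D3:**
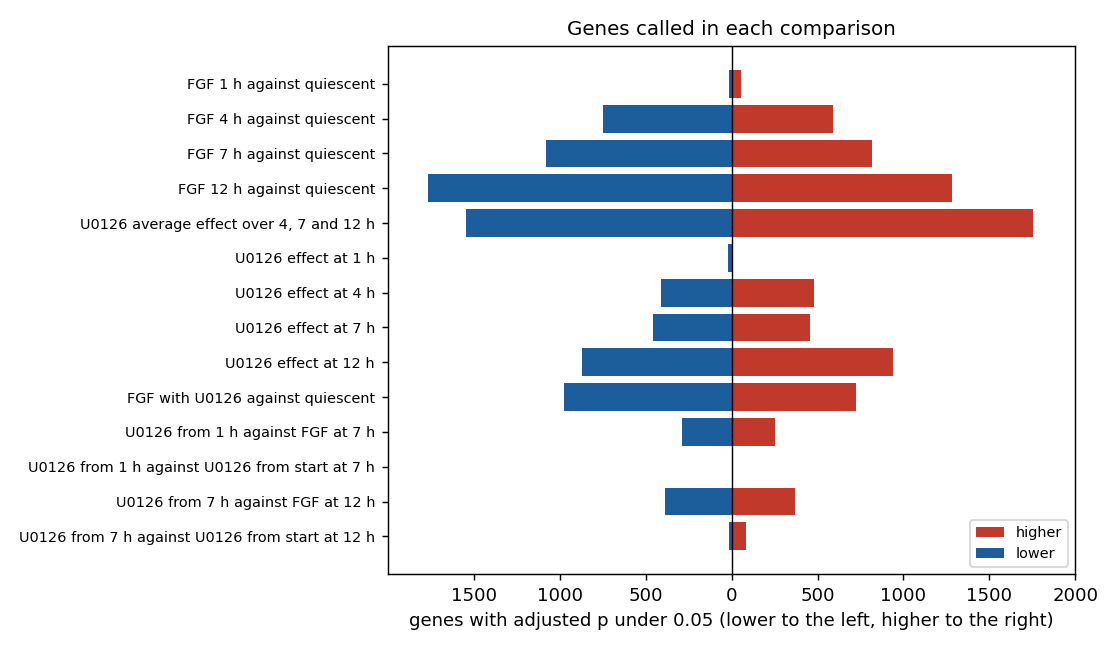
Number of genes with an adjusted p under 0.05 in each of the 14 comparisons, drawn as bars for higher and lower genes. The average U0126 effect had 1752 higher and 1544 lower, and U0126 from 1 h against U0126 from the start had 0.

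The U0126 effect was tested for differences between 4, 7 and 12 h. The 10 genes named for their smallest p-values included the DNA replication genes Prim1, Mcm4 and Cdc45. Prim1 differed by -3.06 ± 0.24 between 12 and 4 h, with effects of 0.17, -1.10 and -2.89 at 4, 7 and 12 h (adjusted p = 8.9e-05). The U0126 effect was also lower at 12 h than at 4 h for Dscc1 (-4.44 ± 0.47), Pbk (-3.53 ± 0.37) and Pclaf (-3.33 ± 0.34). The same held for Cdc45 (-3.18 ± 0.35), Gmnn (-2.79 ± 0.30), Cenpq (-2.49 ± 0.28), Atad2 (-2.44 ± 0.19) and Mcm4 (-2.11 ± 0.19). For Atad2 and Mcm4 the adjusted p was 0.45 and 0.33 with the probe set of highest variance. The growth factor Tgfb3 went the other way, by 2.17 ± 0.21. Ccne1 (-2.50 ± 0.43), Bub1 (-3.05 ± 0.42), Birc5 (-2.82 ± 0.45), Ccl2 (-2.00 ± 0.40), Pik3ip1 (1.59 ± 0.30), Hbp1 (1.44 ± 0.22) and Pdcd4 (1.00 ± 0.20) differed as well. For Dusp6 (0.60, adjusted p = 0.6), Ccnd1 (0.29, 0.84), Egr1 (-0.68, 0.87) and Jund (0.86, 0.73) no difference between times was found. The effect differed for 154 genes, and the block gave 576. The count was 70 without FGF 4 h replicate 2, 89 without U0126 4 h replicate 1, 43 and 94 without FGF 12 h replicate 1 and replicate 2 and 60 without U0126 12 h replicate 2.

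Cells given FGF with U0126 did not simply match quiescent cells (6 samples over 4, 7 and 12 h against 2). Nr4a3 (4.10 ± 0.42), Npas4 (3.23 ± 0.37), Hbb-bh1 (2.94 ± 0.23), Slc7a11 (2.85 ± 0.19) and Atf3 (2.80 ± 0.18) were most raised. Egr1 (-5.57 ± 0.24), the thioredoxin inhibitor Txnip (-3.30 ± 0.39), Egr2 (-2.87 ± 0.35), Fos (-2.80 ± 0.35) and the retinoic acid hydroxylase Cyp26b1 (-2.63 ± 0.33) were most lowered. The stress list was higher in 18 of 24 cases, 19 adjusted over the list alone, with a mean of 0.93 (adjusted p = 2e-21; adjusted p = 0.013 with an estimated correlation). They included Ddit3 (1.95 ± 0.15), Mthfd2 (1.82 ± 0.19), Sdf2l1 (1.74 ± 0.13) and Gadd45a (1.01 ± 0.15). FOXO targets were lower in 9 of 15 cases, and 11 lower and 1 higher adjusted over the list alone (mean -0.83; adjusted p = 0.013 with an estimated correlation). They included Fbxo32 (-1.78 ± 0.19), Ccng2 (-1.63 ± 0.20) and Pik3ip1 (-1.36 ± 0.17). Cholesterol synthesis genes were higher in 12 of 20 cases, 12 adjusted over the list alone (mean 0.63; adjusted p = 3.3e-15; adjusted p = 0.095 with an estimated correlation). They included Lss (1.31 ± 0.16), Fdps (0.99 ± 0.12) and Sqle (0.78 ± 0.09). Ribosome biogenesis genes were higher in 18 of 31 cases, 24 adjusted over the list alone (mean 0.53; adjusted p = 7e-17; adjusted p = 0.051 with an estimated correlation). Growth factor receptors were lower in 9 of 15 cases and higher in 1, 10 and 1 adjusted over the list alone (mean -0.69; adjusted p = 6.7e-09; adjusted p = 0.051 with an estimated correlation), with Pdgfra at -1.87 ± 0.14 and Pdgfrb at -1.58 ± 0.16. In the antiproliferative list 2 were higher and 15 lower, 3 and 15 adjusted over the list alone (mean -0.36; adjusted p = 0.0023; adjusted p = 0.26 with an estimated correlation). They included Mxd4 (-1.36 ± 0.15), Pdcd4 (-1.25 ± 0.12) and Dab2 (-0.99 ± 0.11). Fosl1 stayed 1.89 ± 0.19 above quiescence, Ptgs2 2.29 ± 0.18, Hk2 1.73 ± 0.15 and Plaur 1.54 ± 0.12, while Ccnd1 was at -0.73 ± 0.13 (adjusted p = 0.089 without quiescent replicate 2). The G1/S list had 1 higher and 7 lower, 1 and 12 adjusted over the list alone (mean -0.27; adjusted p = 0.0043; adjusted p = 0.65 with an estimated correlation), and ERK targets averaged 0.21 (adjusted p = 0.24). For immediate-early genes the mean was -0.04, the median 0.11 and the test's direction up (adjusted p = 0.53). Dusp6 (0.12 ± 0.13), Ccne1 (0.36 ± 0.25), Cdkn1a (0.11 ± 0.21), Cdkn1b (-0.37 ± 0.23), Tob1 (0.33 ± 0.21; adjusted p = 0.026 with the block), Jund (0.16 ± 0.22), Klf4 (0.00 ± 0.15) and Myc (0.40 ± 0.13, 0.058; 0.0093 with the block) did not pass. The count was 1700, 723 higher and 977 lower, of which 1665 (97.9%) moved the same way in every pair, with 3146 with the block. It was 516 without quiescent replicate 2 (266 higher, 250 lower). The excess of lower genes also turned over under 75th percentile scaling, with 822 higher and 797 lower.

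U0126 added 1 h after FGF gave changes at 7 h close in size to those of the inhibitor given from the start. Against FGF alone Nr4a3 (4.62 ± 0.63), Car6 (3.61 ± 0.49), Fibin (3.41 ± 0.33), the muscle caveola protein Cavin4 (3.36 ± 0.49) and Ddit3 (3.24 ± 0.23) rose most. Ccl2 (-4.86 ± 0.35), Timeless (-4.06 ± 0.68), Tslp (-3.93 ± 0.37), Hmga2 (-3.39 ± 0.38) and Ccl7 (-3.38 ± 0.39) fell most, in 1 sample against 2. Mcm5 (-3.33 ± 0.33), Etv5 (-3.32 ± 0.26), Ereg (-2.99 ± 0.22), Uhrf1 (-2.99 ± 0.28), Dusp6 (-2.72 ± 0.20), Egr1 (-2.50 ± 0.36) and Ccnd1 (-2.35 ± 0.20) fell. Atf3 (3.13 ± 0.28), Gadd45a (2.75 ± 0.22), Jund (2.26 ± 0.33) and Mmp14 (1.65 ± 0.18) rose. Ccnd1 signal was 5689 ± 36 with FGF, 1338 ± 235 with U0126 from the start (SD, 2 arrays each) and 1104 with U0126 from 1 h. Fosl1 fell by 1.36 ± 0.28, with an adjusted p of 0.061 without FGF 7 h replicate 1 and 0.084 without a variance trend. ERK targets averaged -1.52 (12 of 21 lower; 15 adjusted over the list alone; adjusted p = 0.0075 with an estimated correlation). G1/S genes averaged -1.39 (24 of 47 lower; 37 adjusted over the list alone; adjusted p = 0.024 with an estimated correlation) and stress genes 1.13 (14 of 24 higher; 21 adjusted over the list alone; adjusted p = 0.0075 with an estimated correlation). The antiproliferative list averaged 0.30, with 6 higher and 1 lower, 9 and 3 adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.47 with an estimated correlation). Ccne1 (-1.33 ± 0.37, 0.067; 0.012 with the block), Klf4 (0.82, 0.06; 0.016 with the block), Tob1 (0.94, 0.14; 0.0069 with the block) and Cdkn1a (0.83, 0.22; 9.8e-05 with the block) did not pass. In all 539 genes changed, 252 higher and 287 lower, with 1126 with the block; the count was 295 without FGF 7 h replicate 2. Under 75th percentile scaling the balance turned over, with 298 higher and 249 lower.

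Set directly against U0126 from the start at 7 h, the addition at 1 h changed 0 genes with limma. An unadjusted p under 0.05 was reached by 440 of 14996 genes, fewer than chance alone would give. The block gave 4, Egr1, Mgp and Timp1 higher and Denn2b lower (the last 3 named after their values were seen), and each replicate left out in turn gave 0. The largest difference among the fixed genes was Egr1, at 1.76 ± 0.36 (adjusted p = 0.62; 1.94 and 0.016 with the block), with signals of 295.6 for the addition at 1 h and 77.6 ± 5.23 (SD, 2 arrays) from the start. Fosl1 (-0.12 ± 0.28), Dusp6 (-0.35 ± 0.20), Ccnd1 (-0.26 ± 0.20), Ccne1 (-0.47 ± 0.37), Jund (-0.17 ± 0.33), Tob1 (-0.06 ± 0.32), Cdkn1a (-0.09 ± 0.32), Cdkn1b (-0.13 ± 0.35), Klf4 (-0.18 ± 0.22), Myc (-0.01 ± 0.19), Fos (-0.55 ± 0.53) and Spry4 (0.19 ± 0.47) did not pass. Genes raised by U0126 at 4 and 12 h, chosen from a contrast that holds no arrays of the 7 h comparison, numbered 1349. They had a median of 0.48 for the addition at 1 h against FGF. This was 96.9% of the 0.49 seen with U0126 from the start, with 241 higher where 22.7 were expected. The 1148 lowered genes had a median of -0.54, 94.4% of -0.57, with 255 lower where 22 were expected. The medians against U0126 from the start were -0.03 and 0.02, small but outside the central range of random sets (-0.02 to 0.01). G1/S genes averaged 0.03 in that comparison (adjusted p = 0.74). Small shifts of ribosome biogenesis (0.17; adjusted p = 0.53 with an estimated correlation), ERK target (-0.21; adjusted p = 0.54 with an estimated correlation) and stress genes (0.11; adjusted p = 0.54 with an estimated correlation) rested on the preset correlation.

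The inhibitor added at 7 h still changed transcripts by 12 h. Against FGF alone Hmga2 (-4.92 ± 0.38), Ccl2 (-4.54 ± 0.35), Tslp (-4.36 ± 0.37), Etv5 (-4.10 ± 0.26) and Gpr149 (-3.27 ± 0.42) fell most. Nr4a3 (4.54 ± 0.63), Hbb-bh1 (3.99 ± 0.34), the histone deacetylase Hdac9 (3.45 ± 0.70), Npas4 (3.39 ± 0.56) and Sox6 (3.20 ± 0.31) rose most, in 1 sample against 2. With an offset of 1 Hdac9 was 1.44 (adjusted p = 0.62). Egr1 (-3.06 ± 0.36), Dusp6 (-2.66 ± 0.20), Ccnd1 (-2.14 ± 0.20), Fosl1 (-2.11 ± 0.28), Msh6 (-1.91 ± 0.17), the histone chaperone Nasp (-1.78 ± 0.20) and Cdt1 (-1.77 ± 0.18) fell. Ddit3 (2.97 ± 0.23), Herpud1 (2.48 ± 0.20), Jund (2.45 ± 0.33), Gadd45a (1.94 ± 0.22) and Ndrg1 (1.79 ± 0.23) rose. Ccnd1 signal was 5682 ± 416 with FGF (SD, 2 arrays) and 1275 with U0126 from 7 h. Myc fell by 0.91 ± 0.19, Tob1 rose by 1.30 ± 0.32 and Klf4 by 0.90 ± 0.22; without FGF 12 h replicate 2 their adjusted p was 0.087, 0.16 and 0.19, and without a variance trend 0.076, 0.13 and 0.13. With the probe set of highest variance Klf4 was 0.01 (adjusted p = 0.99). ERK targets averaged -1.51 (13 of 21 lower; 14 adjusted over the list alone; adjusted p = 0.0097 with an estimated correlation). Stress genes averaged 1.2 (15 of 24 higher; 22 adjusted over the list alone; adjusted p = 0.0097 with an estimated correlation) and G1/S genes -1.23 (25 of 47 lower; 37 adjusted over the list alone; adjusted p = 0.03 with an estimated correlation). The antiproliferative list averaged 0.59, with 9 higher and 1 lower, 9 and 1 adjusted over the list alone (adjusted p = 6.1e-07; adjusted p = 0.095 with an estimated correlation). Ribosome biogenesis genes averaged -0.52 (7 of 31 lower; 15 adjusted over the list alone; adjusted p = 0.097 with an estimated correlation) and cholesterol synthesis genes 0.54 (4 of 20 higher; 7 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). Ccne1 (-1.23 ± 0.37, adjusted p = 0.076; 0.015 with the block), Cdkn1a (0.81 ± 0.32, 0.18; 0.00011 with the block), Cdkn1b (0.83 ± 0.35, 0.22; 0.12 with the block), Fos (0.29 ± 0.53, 0.85) and Spry4 (-0.51 ± 0.47, 0.66) did not pass. The 1044 genes raised by U0126 at 4 and 7 h had a median of 0.62, 101% of the value with U0126 from the start at 12 h, with 297 higher where 25.8 were expected. The 962 lowered genes had a median of -0.58, 106% of -0.54, with 286 lower where 24.8 were expected. Against U0126 from the start the medians were -0.02 and -0.01, but 53 of the lowered genes were higher with the later addition, where 5.39 were expected. There were 758 changed genes, 371 higher and 387 lower, a balance that turned over under 75th percentile scaling (396 and 334) and quantile normalization (414 and 379) and without FGF 12 h replicate 1 (264 and 210), and 1695 with the block. Counts were 474 and 368 without FGF 12 h replicate 1 and replicate 2.

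Replication genes separated the addition at 7 h from U0126 given from the start. At 12 h Tk1 (3.93 ± 0.56), the mitotic checkpoint gene Kntc1 (3.54 ± 0.57), Pclaf (3.39 ± 0.29), Cdc6 (3.29 ± 0.54) and the matrix Gla protein Mgp (3.05 ± 0.24) were higher with the later addition, in 1 sample against 2. Mcm5 (3.02 ± 0.33), Pole (2.92 ± 0.31), Bub1 (2.66 ± 0.36), Prim1 (2.27 ± 0.21), Timp1 (2.02 ± 0.17) and Mcm7 (2.01 ± 0.21) were higher too. Cdc6 signal was 430.5 with U0126 from 7 h and 33.95 ± 20.2 from the start (SD, 2 arrays). Without a variance trend the adjusted p of Tk1, Kntc1 and Cdc6 was 0.073, 0.1 and 0.08, without U0126 12 h replicate 2 it was 0.074 for Kntc1 and 0.096 for Cdc6, and with an offset of 1 it was 0.051 for Cdc6. The G1/S list averaged 1.46, with 25 of 47 higher and 37 adjusted over the list alone (adjusted p = 4.7e-54; adjusted p = 0.023 with an estimated correlation). G2/M genes averaged 1.27 (3 of 33 higher; 16 adjusted over the list alone; adjusted p = 4.3e-23; adjusted p = 0.17 with an estimated correlation). Cholesterol synthesis genes averaged 0.68 (1 of 20 higher; 18 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation) and stress genes 0.36 (2 of 24 higher; 6 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). ERK targets had 0 called, 1 higher and 2 lower adjusted over the list alone (mean -0.26; adjusted p = 0.0037; adjusted p = 0.32 with an estimated correlation), and the antiproliferative list did not shift (-0.08, adjusted p = 0.3). The endoplasmic reticulum stress gene Herpud1 rose by 1.80 ± 0.20, and Ccne1 by 1.86 ± 0.37 with calls lost without U0126 12 h replicate 1 (adjusted p = 0.051) or replicate 2 (0.24), a filter (0.062) or a variance trend (0.14). Lower genes were 1700001G17Rik (-2.83 ± 0.52), Tnfrsf25 (-2.14 ± 0.40), Npn2 (-2.11 ± 0.45), Sting1 (-2.10 ± 0.42) and Foxo4 (-1.91 ± 0.33), whose adjusted p without U0126 12 h replicate 2 was 0.15, 0.19, 0.19, 0.13 and 0.13. All 5 also lost the call without a variance trend. Without U0126 12 h replicate 1 it was 0.054 for 1700001G17Rik, 0.16 for Npn2 and 0.15 for Sting1. Dusp6 (-0.52 ± 0.20), Ccnd1 (-0.50 ± 0.20), Egr1 (1.23, adjusted p = 0.2; 0.0067 with the block), Fosl1 (-0.13), Jund (-0.20), Tob1 (0.33), Cdkn1a (0.12), Cdkn1b (-0.05), Klf4 (-0.08) and Myc (-0.67) did not pass. The count was 101 genes, 84 higher and 17 lower, 16.8% lower. With the block it was 335, 222 higher and 113 lower (33.7% lower), and without U0126 12 h replicate 2 it was 33, 31 higher and 2 lower (6.06% lower). Without a variance trend it was 21, 20 higher and 1 lower (4.76% lower).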

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

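The effect of U0126 depended on time for 154 genes in a test of the difference itself. Between 12 and 4 h the effect differed by -4.44 for Dscc1, -3.53 for Pbk, -3.33 for Pclaf, -3.18 for Cdc45, -3.06 for Prim1, -2.79 for Gmnn, -2.49 for Cenpq, -2.44 for Atad2, -2.11 for Mcm4 and 2.17 for Tgfb3 (log2). List tests of the difference between 12 and 4 h were not among the comparisons chosen beforehand. List means differed by -2.21 for G1/S and 0.47 for FOXO targets (adjusted p = 0.0074 and 0.045 with an estimated correlation). Under the preset correlation alone they also differed by -1.52 for G2/M, 0.37 for antiproliferative genes, -0.24 for ribosome biogenesis, -0.29 for cholesterol synthesis, 0.34 for matrix, -0.31 for the stress response and -0.52 for inflammation. Outside the comparisons, 510 of 6622 probe sets without a single gene changed in the average U0126 effect, 230 higher and 280 lower.

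The larger fall of G1/S genes at 12 h was weighed against technical explanations fixed before their results were seen. Little room to fall at low signal was argued against by the 23 members brightest in quiescent cells, which differed by -1.98 (SD 0.69), near the -2.44 of the 24 dimmer ones. A difference between experiments was argued against by -2.18 and -2.25 in them, and scaling by -2.23 under quantile normalization and -2.17 under 75th percentile scaling. The difference arose in the arm with FGF alone, where the list mean against quiescence was 0.21 (SD 0.25) at 4 h and 2.51 (SD 0.19) at 12 h. With U0126 from the start it was -0.26 (SD 0.15) and -0.18 (SD 0.15), so by 12 h there was more to lose. Whether the cells of the arms progressed alike was not measured.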

How the results depend on the processing

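Single arrays and pairs of arrays set the limits: counts near the adjusted p of 0.05 move with the variance estimate, and low signals are compressed by the offset. Of 14823 values of named genes under alternatives, 13862 were kept, 895 lost the call, 54 gained it and 12 reversed. A value called in neither fit counted as kept even where its sign changed. Without 1 replicate 4348 were kept, 498 lost and 13 gained. Of 408 list values 301 were kept and 107 lost, 97 with an estimated correlation, 5 under quantile normalization and 5 with the block.

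Taking experiment as a block, which the pairing called for, raised counts to 236, 2658 and 3250 for FGF at 1, 4 and 7 h, 158, 1946, 1882 and 3095 for U0126 at 1, 4, 7 and 12 h, 576 by time, 3146 for FGF with U0126 against quiescence, 1126 for U0126 from 1 h against FGF, 4 against U0126 from the start, 1695 for U0126 from 7 h against FGF and 335 against U0126 from the start.

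Counts fell without a variance trend to 42 and 852 for FGF at 1 and 4 h, 578 and 524 for U0126 at 4 and 7 h, 46 by time, 1064 for FGF with U0126, 299 for U0126 from 1 h against FGF, and 376 and 21 for U0126 from 7 h against FGF and against U0126 from the start. With only the compared groups FGF at 7 h gave 1097, and U0126 at 4 and 7 h gave 538 and 573. For these settings the cause was not tested.

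With the probe set of highest variance FGF at 4, 7 and 12 h gave 817, 1135 and 2012, U0126 538, 595 and 1157, by time 68, FGF with U0126 1026, U0126 from 1 h 344 and from 7 h 464 against FGF. It reversed 4930431P19Rik (0.52 at 1 h of FGF), Insr (0.08 at 4 h), Fhl1 (0.83 at 7 h, 0.31 at 12 h), Ing1 (0.36) and Plat (0.16) in the average effect, Plat at 7 h (0.02), in FGF with U0126 (0.72) and from 1 h (0.55), Snhg5 with U0126 at 1 h (-0.17), and Fdft1 (-0.11) and Fbln2 (0.06) in FGF with U0126. By construction it reads other probes. Among all probe sets, which are more than genes, FGF at 12 h gave 4839, the average effect 5681, U0126 at 12 h 2733 and FGF with U0126 2559. Genes lowered at 4 and 12 h had -0.48 from 1 h under quantile normalization; the cause was not tested.

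Leaving out 1 replicate at a time gave counts from 47 to 95, 548 to 1383, 868 to 2057 and 1733 to 3079 for FGF at 1, 4, 7 and 12 h. For U0126 at 4, 7 and 12 h they ranged from 436 to 539, 491 to 600 and 984 to 1153, and by time from 43 to 155. The other ranges were 516 to 1890 for FGF with U0126, 295 to 499 for U0126 from 1 h against FGF, 368 to 474 for U0126 from 7 h against FGF and 33 to 80 against U0126 from the start. The lowest values for FGF at 1, 7 and 12 h and for FGF with U0126 came without quiescent replicate 2, and for FGF at 4 h without FGF 4 h replicate 2. Fewer samples lower the power by construction. The average effect, at 2833 to 3137, stayed within 1.5 times of 3296 but below it, and U0126 from 1 h against U0126 from the start stayed at 0.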

Other observations

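Tests of the stress list against experiments, return to quiescence, time or FGF alone and compound action, and both tests of U0126 from 1 h, were chosen after the results were seen. ATF4 target, chaperone and CREB target lists were written after the main results and before their own test. Outside the lists of the report, U0126 raised further genes of amino acid supply and the integrated stress response in its average effect: Gpt2 by 1.56 ± 0.12, Cth by 1.52 ± 0.18, Nupr1 by 1.48 ± 0.12, Ppp1r15a by 1.46 ± 0.12, Pck2 by 1.14 ± 0.13, Jdp2 by 1.14 ± 0.08 and Slc1a4 by 1.05 ± 0.10. The 8 ATF4 targets that did not pass were Slc7a1 (0.30), Iars (0.28), Shmt2 (0.25), Cars (0.23), Tars (0.19), Cebpg (0.16), Mthfd1l (-0.17) and Slc1a5 (-0.20). Chaperone-related genes rose too, Creld2 by 0.79 ± 0.10, Edem1 by 0.69 ± 0.10 and Dnajb11 by 0.57 ± 0.09.

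That U0126 raised stress genes through ATF4 is a hypothesis. With limma's camera and an estimated correlation, ATF4 targets outside the stress list averaged 0.67, with 18 of 26 higher (adjusted p = 0.0477). Endoplasmic reticulum chaperones averaged 0.35 with 8 of 15 higher (adjusted p = 0.0756), and in FGF with U0126 against quiescence 0.60 with 11 of 15 higher (adjusted p = 0.0103), where ATF4 targets averaged 0.72 (adjusted p = 0.0103). The chaperones thus passed in some comparisons and not in the average effect, which leaves their part open. For U0126 from 7 h against FGF the means were 0.69 and 0.65 (adjusted p = 0.0434 and 0.0402). CREB targets, which might go with the rise of Nr4a genes, averaged 0.22 with 2 of 10 higher and 1 lower (adjusted p = 0.287), so that this stays open.

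The stress list was also higher with U0126 than in quiescent cells, by 0.93 (SD 0.3 over 6 values that share the quiescent samples). This is more than a mere return after FGF had lowered the genes would give. The value is the observation itself and not a separate test. FGF without the inhibitor gave -0.07 (SD 0.16), which argues against time in culture. Experiments gave 0.82 and 1.04, and scaling 0.95 by quantile and 0.97 by 75th percentile, which argues against both. An action of the compound apart from MEK cannot be told apart from MEK inhibition, because 0 arrays had the inhibitor and no FGF. Both may contribute, and a second MEK inhibitor would be needed to separate them.

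U0126 from 1 h retained a difference from U0126 from the start of 4.86% of the inhibitor's effect at 7 h, as a median over 2497 genes called at 4 and 12 h. Against experiment 1 alone the share was 0.693% and against experiment 2 6.74%, so the share was larger against the other experiment but small against both. A median over the set can hide differences of its parts, as for the addition at 7 h, where it was near 0 although G1/S genes averaged 1.46. On simulated data without an experiment effect the comparison recovered 28% of 2-fold and 63.5% of 4-fold changes. Too little power with 1 array therefore stays open for single genes such as Egr1 and for smaller groups. The first hour of MEK activity may leave little of the response at 7 h in the set as a whole.

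Changes were also correlated across genes already called for U0126 at other times. This leaves out unchanged genes and can raise r. The addition at 1 h in experiment 1 and U0126 from the start in experiment 2 gave r = 0.89 (2497 genes). For the addition at 7 h r was 0.85 (2006 genes). Genes are not independent replicates.

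For the average U0126 effect, 1 of 100 splits drawn from 108 ways to divide the 12 arrays gave as many genes, the real one with 3296. The highest other gave 974; it followed U0126 at 2 of the times and parted 4 pairs. Among 27 others that part 6 pairs, as the real one does, the highest was 692 and the median 0. The split that followed the experiment gave 0. Splits that mix the arms put the U0126 effect into the spread within groups, so few calls were to be expected from them. The replicates may also be technical, so these splits cannot exclude chance.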
